A study of Mus musculus with 8 samples.

How the data were processed

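Per the labels' protocols, atrial tissue was frozen on dry ice, RNA was extracted with a column kit, and libraries were made from total RNA with an Illumina TruSeq RNA kit. Per the submitters' processing notes, the tools used were cutadapt 2.3, FastQC 0.11.8, STAR 2.7.3a, RSEM 1.3.2 and DESeq2, and the genome build was GRCm38. Their roles and settings, and the gene annotation, are not given in the sources used here. The authors deposited 1 table for the whole series, named as raw counts per gene.

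The samples were grouped by genotype from their titles, 4 marked WT and 4 marked KO, here called wild type and Scn1b null. All were at postnatal day 16. The table's columns were then compared by name with the labels. A match required the whole column name, with or without its Sample prefix, to occur as exact text. Its 8 columns of per-sample values are named by a numbering scheme, from 1 to 8, that appears in no label, so all 8 were left out, and no value in them enters any result. Only the column names and the gene identifiers were used.

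A quasi-likelihood test of null against wild type on the counts was planned before the data were examined. So were tests of gene lists, from a prepared set of 45, and a set of processing alternatives. None of these was run, because no column could be given a genotype. The prepared lists comprised 9 for ion channels, calcium handling, matrix, TGF-beta signalling, junctions, autonomic genes, receptors and cardiac stress. Another 19 covered other processes, and 17 held markers of cell types, the mitochondrial genome and the sex chromosomes. The sex chromosome list was to be left out of the tests.

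Gene identifiers were matched to GENCODE M21 by their Ensembl number without its version, with Python 3.11.15 and pandas 2.3.3. Coordinates are those of GENCODE M21 on GRCm38, the build named in the submitters' processing notes, counted from 1. List members were matched by gene symbol, with an alternative symbol, older or newer, accepted where one was recorded beforehand.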

Results

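RNA was sequenced from the atria of 16-day-old mice of 2 genotypes, wild type and Scn1b null. Scn1b encodes a beta subunit of voltage-gated sodium channels, which modulates the pore-forming subunit and takes part in cell adhesion. Going by the series title, the study was concerned with fibrosis and atrial fibrillation in the null animals. The labels describe 8 samples, 4 wild-type and 4 null, numbered 1 to 4 within each genotype. They give no sex, litter, collection day or sequencing batch. The design implies 1 comparison, null against wild-type atria at postnatal day 16.

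This comparison was not made. The deposited table holds 8 columns of values, numbered 1 to 8 by a scheme that occurs in none of the sample labels. Of these columns, 0 could be matched by name, as exact text, to a sample or to a genotype. The replicate numbers do not settle the match, because the numbers 1 to 4 occur in both genotypes. No label ties the order of the columns to the samples, so genotypes were not assigned from it. They were not assigned from the Scn1b values either, since these are what would check the genotype labels. Without a match there is no fold change or test, and nothing is stated about which genes differed between the genotypes. Expression levels and depths over all columns were not analysed here. They would need no genotype, but only columns whose names matched a sample were to be used.

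The gene rows of the table do not depend on that match. The table lists 30608 genes, each once, by Ensembl mouse gene identifier. Of these, 30538 (99.8%) were found in GENCODE release M21 on GRCm38, and 70 were not. Protein-coding genes made up 18822 of the matched identifiers (61.6%). They were followed by 2794 processed pseudogenes, 2694 long intergenic non-coding RNAs, 2157 genes of the annotation's class TEC, which awaits experimental evidence, and 2047 antisense genes. A further 24912 genes of the annotation have no row in the table. Whether they were removed by a filter is not given in the sources used here.

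Scn1b (ENSMUSG00000019194) has a row. In GENCODE M21 on GRCm38 it lies on the minus strand of chromosome 7, from 31116524 to 31127003, a span of 10480 bp. It has 3 annotated transcripts. Scn1b-201 is protein-coding with 6 exons, Scn1b-203 is protein-coding with 5 exons, and Scn1b-202 is a retained-intron transcript with 3 exons. The annotation places 0 other genes over the Scn1b span. Its nearest neighbours are Hpn, on the same strand from 31098725 to 31115290, and Gramd1a, also on the minus strand, from 31130127 to 31155896. Both neighbours have rows in the table.

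Rows were also looked up for the genes of the prepared lists. All 13 other sodium channel genes of the prepared list have a row, including Scn5a, the main cardiac pore-forming subunit, and the other beta subunits Scn2b, Scn3b and Scn4b. So do all 47 collagen and fibrotic matrix genes, among them Col1a1, Col3a1 and Postn, and all 31 TGF-beta pathway genes. The 31 potassium channel genes, 29 calcium handling genes and 25 gap junction and intercalated disc genes are complete as well. So are the 26 autonomic neuron genes, 26 adrenergic and muscarinic receptor genes and 24 cardiac stress and hypertrophy genes. A row shows only that a gene was listed, not that its RNA was detected in atria.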

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

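No paired analysis was possible because the columns of the table carry no replicate number or genotype that the labels use. The labels also give no litter or collection day, so equal replicate numbers do not show that wild-type and null samples were pairs. Because the columns could not be matched to samples, no other scaling, filter or test was run, and no fit that leaves out a replicate. The match of gene identifiers to GENCODE M21 was not part of the plan. It was also counted in a stricter way, likewise not planned and chosen after seeing the data. Of the 30538 matched identifiers, 24856 had a GENCODE symbol that is also a symbol or synonym in the RefSeq gene table. This count is a part of the same match, so it cannot show whether the match depends on the method.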

Other observations

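Of the 45 prepared gene lists, 44 had a row in the table for every member. Counted by symbol, 840 of the 843 distinct members were listed. The share of all annotated protein-coding genes with a row was not counted, so the lists cannot be set against it. The exception was the list of red cell markers, with 10 of its 13 members. Ahsp, Hbb-b1 and Hbb-b2 had no row under those symbols. The list's other Hbb symbols, Hbb-bs and Hbb-bt, had rows.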
